A study of Mus musculus with 24 samples.

How the data were processed

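Islet cells of NOD/ShiLtJ mice were measured with the 10x Genomics 5' chemistry, which counts messenger RNA molecules per cell by unique molecular identifiers (UMIs) and reads T cell receptor transcripts from the same cells. Per the labels, islets were freed with collagenase and picked by hand, the cells of each animal were marked with a hashtag antibody, and the marked cells were pooled. The pool was then split into 4 libraries, each sequenced in 2 runs. The 24 samples are 3 kinds of library (gene expression, receptor and hashtag) for each library and run. Gene and hashtag counts in the files are whole-number UMI counts per barcode, as deposited. The authors' receptor tables hold counts of reads and UMIs per contig and, per clonotype, a count of cells and that count as a fraction of all cells with a clonotype. Cell Ranger 4.0.0, Scanpy and the genome builds GRCm38 and mm10 were used per the submitters' processing notes, which give no role or order. Other settings of that processing are not given in the sources used here. The hashtag samples have no table of their own here, and the hashtag counts were taken from the gene expression tables. The number of columns belonging to other samples was 0.

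The labels name 6 mice, 3 on each of 2 diets, while the tables hold 9 hashtags, and no source used here pairs a hashtag with a diet or an animal number. Diets were therefore not compared, and no diet was inferred for any hashtag. Cells of 1 hashtag are called a hashtag group (S1 to S9) and were taken as 1 animal. The mice were 15 weeks old per the sample labels and 16 weeks per the series text. The 9 groups were used to compare classes of cell within the same groups. No sets of groups were compared, and values of single groups were only screened for one that stood apart from the others. The 4 libraries split 1 pool, so their spread is technical.

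Run 2 was the main run, since it held more UMIs for the same cells. Between 99.96% and 99.98% of run 1 barcodes per library were also in run 2. The libraries held 7773 ± 652 barcodes in run 1 and 9287 ± 800.8 in run 2 (SD, n = 4). UMIs per barcode, over barcodes of both runs, had a median of 1240 ± 98.3 in run 1 and 2270 ± 171.5 in run 2. Receptor barcodes rose from 2914 ± 240.5 to 3224 ± 262.1. Each of these was higher in run 2 in 4 of 4 libraries (exact sign-flip permutation test, two-sided p = 0.125, the smallest that 4 libraries allow). Of cells with a paired receptor in both runs, 98.4% ± 0.0901 had the same receptor.

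Barcodes were kept with at least 200 genes and at most 10% mitochondrial UMIs. Each hashtag's threshold was set per library by Otsu's method on log counts (scikit-image 0.26.0), and cells above the threshold of 1 hashtag were assigned to it. Cells above several thresholds and cells called doublets by Scrublet (Scanpy 1.11.5) were left out, and clonotypes were taken only from T cells with exactly 1 TRA and 1 TRB chain. Scrublet marked 0 to 2 cells per library and so did not work here, which leaves doublets within 1 hashtag group undetected. Genes have symbols for 32158 of 32285 identifiers. Counts were scaled to 10000 per cell and log-transformed. A graph of 15 neighbours in 30 components of 2000 variable genes was clustered with leidenalg 0.10.2 at resolution 1. Clusters were called X-like from markers of 27 cell types. A name needed a score of at least 0.5, a minimum set after the clusters were seen: it was first absent, then 0.55, then 0.5, after receptor gamma genes were left out and T cell clusters of 3630 and 1053 cells came just under 0.55. The names of alpha-like and beta-like clusters did not depend on it. Numbers were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures with matplotlib 3.10.9.

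A clonotype was a TRA and TRB pair with the same V genes and nucleotide CDR3s, counted over the pool of 4 libraries, and was called expanded from 2 cells up. Where clonotypes are counted by V gene or receptor family, 1 found in 2 hashtag groups counts in each. CD8 T cells had at least 1 UMI of Cd8a or Cd8b1 and none of Cd4, and CD4 T cells the reverse. These 3 genes define the classes and are not named as findings. Of 7602 T cells with a paired receptor, 2002 were CD8, 1844 CD4, 94 had UMIs of both and 3662 (48.2%) of neither. Shares of cells or clonotypes were compared within hashtag groups by exact two-sided sign-flip permutation tests, with Benjamini-Hochberg adjustment over the 6 receptor families. Intervals are exact 95% binomial intervals and the limit for a share of 0 is 3 counts of the total. Both cover counting error only.

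UMIs were summed per hashtag group and class of at least 10 cells (20 for islet cells) and tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, hashtag group as a covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Receptor and immunoglobulin V, D, J and C genes were left out. The difference between the CD8 and CD4 changes was an interaction term in a model of both classes. Fixed gene lists, 14 for T cells and 5 for islet cells, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. DESeq2 1.42.0 was an alternative. Clonotypes per V gene (at least 10 clonotypes, a filter chosen after the data were seen) were tested with edgeR in 6 tables. The tests, samples, gene lists, cell type markers, receptor families and the rule for named genes were fixed before the data were examined. Named genes are those past the threshold, with a mean of at least 20 CPM (UMIs scaled to the library total) and the same direction in every hashtag group, with the 10 largest rises and 10 largest falls, leaving out ribosomal protein, mitochondrial, Gm and Rik genes. Up to 4 members of each list with the smallest p were also named. In islet cells, where only lists were planned, other members of lists are named and were chosen after their values were seen. V genes past the threshold are named up to 8 per table, with the 5 clonotypes of most cells per class. A few items that these rules select are not reported here. Coordinates are from a gene table of GRCm38.p6.

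The tests were tested on simulated data with 200 genes changed by known folds. For CD8 T cells (3656 genes), edgeR recovered 56.7% of genes changed 1.5-fold, 95.5% at 2-fold and 100% at 4-fold, and 4.00% of its calls were unchanged genes. For CD4 T cells (4126 genes), these were 52.2%, 89.6% and 100%, with 6.40% unchanged. For the interaction (4651 genes), they were 16.4%, 58.2% and 92.4%, with 1.77% unchanged. For beta-like against alpha-like cells (7196 genes), they were 70.1%, 98.5% and 100%, with 5.79% unchanged. The V gene tables were also checked on 60 simulated tables each with no difference. These drew every hashtag group from the same V gene shares, so they held counting error but no spread between groups. With TMM, 65% of simulated tables of expanded against single CD8 TRAV clonotypes gave at least 1 call, as did 30% for CD8 TRBV and 36.7% for CD4 TRAV, against 0% to 3.33% without TMM. The other 3 tables gave at most 1.67%. That check was made after the calls were seen, and for those 3 tables the values without TMM, an option listed beforehand, are reported in the place of the TMM calls, whose counts are given with them.

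Alternatives covered run 1, a stricter filter on cells (500 genes, 5% mitochondrial), clusters at resolution 0.5, other definitions of clonotype, expansion and class, cells thinned to 1000 UMIs, cycling cells left out, other scaling, filters and tools, counting cells in the place of clonotypes, and each hashtag group left out in turn. Thinning left out cells with fewer than 1000 UMIs, and kept class and clone size as called at full depth. The diet comparison and its alternatives were not run. Further alternatives were added after the data were seen: the 5% highest Scrublet scores left out, clone size counted in other ways, only T cell-like clusters, the 5 largest clonotypes of each class left out, the library as the replicate unit, other minimums for V genes and cluster names, islet cells with a receptor contig left out, and islet clusters of low UMI counts left out.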

Results

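Islets of NOD/ShiLtJ mice, a strain that develops autoimmune diabetes spontaneously, were profiled by single-cell RNA sequencing together with T cell receptor sequencing. The design names 2 diets, 20% hydrolysed casein and 16% hydrolysed casein with 4% gluten, each given to 3 mice. The tables hold 9 hashtags, none of them paired with a diet in the sources used here, so the diets were not compared. The comparisons are between classes of cell within the same 9 hashtag groups, each taken as 1 animal. In the main run, the 4 libraries held 10392, 8896, 9313 and 8546 barcodes and 39397333, 29433971, 33752818 and 34485811 UMIs of genes. The median UMI count per barcode was 1858, 1608.5, 1745 and 1997. Receptor contigs were found for 3544, 3241, 3207 and 2903 barcodes. Filters left 28836 cells, and 67.8% to 73.6% of barcodes per library carried 1 hashtag.

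The islets held many lymphocytes beside endocrine cells. T cell-like cells were 32.5% ± 2.40 of cells (SD over 4 libraries) and B cell-like cells 20.8% ± 0.909. Alpha-like cells, which make glucagon, were 7.64% ± 0.378, beta-like cells, which make insulin, 7.59% ± 0.588, and delta-like cells, which make somatostatin, 2.52% ± 0.640. Macrophage-like cells were 3.40% ± 0.132, natural killer-like cells 1.72% ± 0.12, mature dendritic-like cells 1.33% ± 0.102 and plasmacytoid dendritic-like cells 1.11% ± 0.129. The libraries split 1 pool, so these SDs are technical. Between hashtag groups the T cell-like share ranged from 29.2% to 42.4% (median 36.2%), the B cell-like share from 13.5% to 29.9% (median 22.1%) and the beta-like share from 2.73% to 6.87% (median 4.92%). Every group lay below the beta-like 7.59% over libraries. Cells of no hashtag group count in the library shares alone, and held a larger beta-like share. Acinar-like cells were 8.15% of library 1 and 0.919%, 1.29% and 0.725% of the others, and their share of library 1 was 4.39% in run 1 and 2.55% with the stricter filter on cells. Clusters with 8.68% ± 1.22 of cells stayed unnamed. In run 1 the T cell-like share was 17.7% with 22.5% unnamed, and with a minimum score of 0.55 for a name it was 16.2% with 25.0% unnamed. Receptor contigs were found in 91.7% of T cell-like cells, and also in most cells of small clusters that carried other names, such as 88.5% of a B cell-like cluster of 468 cells and 77.6% of an alpha-like cluster of 152 cells. A beta-like cluster of 1099 cells had a low UMI count, 0.506 of that of its libraries, and Mlxipl and Meg3 among its leading genes, while another of 999 cells was led by Ins2, Ins1, G6pc2 and Iapp.

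Expanded clones made up a large part of the islet T cells. The 7602 T cells with a paired receptor fell into 5421 clonotypes, of which 573 had at least 2 cells. These 573 held 2754 cells (36.2%), and the largest had 51 cells. Among CD8 T cells, 604 of 2002 (30.2%) belonged to 31 clonotypes of at least 10 cells, and among CD4 T cells 261 of 1844 (14.2%) belonged to 32 such clonotypes. The largest CD8 clonotype, with 51 cells, 50 of them in hashtag group S6 and 1 in S3, paired TRAV16N-TRAJ42 (CDR3 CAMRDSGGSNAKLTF) with TRBV13-3 (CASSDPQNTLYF). The next held 46 cells, 41 with the hashtag of S3 and the rest assigned to no group (TRAV6-1 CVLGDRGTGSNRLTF with TRBV1 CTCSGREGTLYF). A clonotype of 44 cells, all in S2, paired the alpha chain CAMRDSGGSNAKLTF with TRBV10 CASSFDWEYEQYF. One of 40 cells, 39 of them in S6 and the other in no group, used TRAV9N-4 with TRBV5, and one of 39 cells, all in S6, used TRAV13-4-DV7 with TRBV29. Of CD4 T cells, the largest clonotype held 46 cells, 31 in S2 and 15 in S9, and paired TRAV16N-TRAJ23 (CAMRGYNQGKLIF) with TRBV15 (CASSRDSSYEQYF). A clonotype of 30 cells had 27 in S3 and the rest in no group (TRAV12-1 with TRBV17). One of 30 cells lay in S6 (TRAV13D-2 with TRBV31), one of 22 cells in S3 (TRAV13-4-DV7 with TRBV2) and one of 17 cells in S1 (TRAV9-4 with TRBV17). All 10 of these clonotypes were found in all 4 libraries. They were ranked by cells of the class, while the totals given also count cells outside it. In the order given, the CD8 clonotypes held 45, 44, 42, 40 and 38 CD8 T cells. The CD4 clonotypes held 24, 14, 13, 14 and 11 CD4 T cells.

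Almost every clonotype lay within 1 hashtag group. Of 541 clonotypes with at least 2 hashtagged cells, 525 (97.0%) lay in 1 group, against at most 48 in 100 shuffles of the hashtags over cells. The cells of a clonotype lay in its main group in 98.6% of cases. Of 36 pairs of hashtag groups, 23 shared no such clonotype and none shared more than 2, while shuffling gave at least 29 for every pair. Across libraries, which split 1 pool, 478 of the 573 clonotypes were seen in at least 2 libraries, against 472 to 517 in 100 shuffles of cells over libraries (permutation p = 0.0297). This p and those of the other settings are one-sided, for a count as low, and no two-sided p was computed. The observed count lay below the shuffled mean of 496.5. The one-sided test did not pass for clonotypes of at least 3 cells (293 shared, permutation p = 0.366) or in run 1 (434 shared, permutation p = 0.129). With clonotypes set by the TRB chain alone it passed, with 592 of 738 shared against 614 to 670 in the shuffles (permutation p = 0.00990, the smallest that 100 shuffles allow).

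The share of T cells in expanded clonotypes was compared between CD8 and CD4 T cells of the same hashtag groups. In CD8 T cells it had a median of 48.1% and ranged from 19.4% (S5) to 70.9% (S7). In CD4 T cells the median was 43.5%, with a range from 24.8% (S4) to 55.8% (S8). Both medians lay above the 36.2% of all paired T cells, which include the cells of neither class. With classes set from at least 2 UMIs the medians were 54.1% and 50%. The shares thus hold for cells with a detected class gene, and not for all CD8 or CD4 T cells. The share was higher in CD8 T cells in 6 of 9 groups, by a median of 6.18 percentage points (range -9.53 to 23.1; exact two-sided sign-flip permutation p = 0.145). It passed the threshold with expansion defined from 3 cells up (p = 0.0469, exact permutation test). It also did with clone size counted among cells of the 2 classes alone (p = 0.0117, exact permutation test), an option added after the data were seen. The medians there were 47.9% in CD8 and 37.2% in CD4 T cells. That option drops cells of neither class, and the largest CD4 clonotype had 24 of 46 cells in its class, the largest CD8 one 45 of 51. Its pass therefore cannot be told from weaker detection of the CD4 class gene. With the 5 largest clonotypes of each class left out, also added after the data were seen, the share was higher in CD8 T cells in 4 of 9 groups. The median difference turned to -0.872 points (exact permutation p = 0.410). The largest clone of each group held a median of 11.8% of CD8 T cells (6.45% to 23.4%) and 5.29% of CD4 T cells (2.96% to 10.4%).

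**Figure D1:**
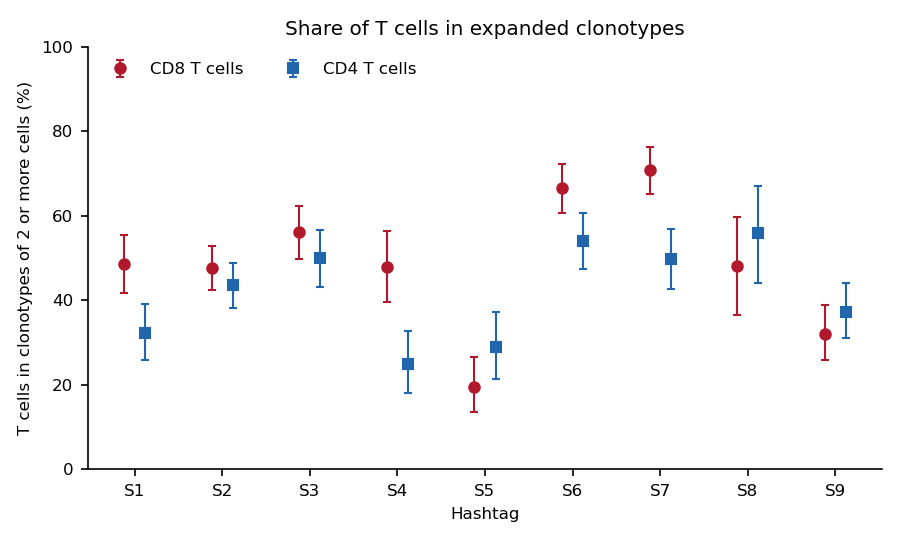
Percent of T cells in clonotypes of at least 2 cells (vertical axis) in each of the 9 hashtag groups (horizontal axis), with circles for CD8 and squares for CD4 T cells and bars for exact 95% binomial intervals. The CD8 share lay above the CD4 share in 6 of 9 groups, and ranged from 19.4% to 70.9%.

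Several receptor families with a known meaning were used to different degrees by CD8 and CD4 clonotypes. Alpha chains of TRAV16-family genes with TRAJ42, the pair used by the islet-reactive CD8 clone 8.3 that recognises a peptide of IGRP, were found in 44 of 1138 CD8 clonotypes (3.87%, 95% CI 2.82 to 5.16) and 3 of 1348 CD4 clonotypes (0.223%, CI 0.0459 to 0.649). The share was higher in CD8 in 9 of 9 hashtag groups (exact permutation p = 0.0039, adjusted p = 0.0117). TRAV5D-4, reported in T cells that recognise an insulin B chain peptide, was found in 18 CD8 clonotypes (1.58%, CI 0.940 to 2.49) and 65 CD4 clonotypes (4.82%, CI 3.74 to 6.11; exact permutation p = 0.0078, adjusted p = 0.0156). TRBV1 was found in 44 CD8 (3.87%) and 104 CD4 clonotypes (7.72%, CI 6.35 to 9.27; exact permutation p = 0.0039, adjusted p = 0.0117); when cells were counted in the place of clonotypes, p was 0.617 (exact permutation test). Counting cells moved other mean differences between CD8 and CD4 away from 0, from 3.74 to 13.5 points for TRAV16-TRAJ42, from 3.14 to 13.1 for the TRBV13 family and from -3.14 to -5.65 for TRAV5D-4. The TRBV13 family was found in 218 CD8 (19.2%, CI 16.9 to 21.6) and 214 CD4 clonotypes (15.9%, CI 14.0 to 17.9; exact permutation p = 0.035, adjusted p = 0.0422), higher in CD8 in 7 of 9 groups. The alpha chain of invariant natural killer T cells, TRAV11 with TRAJ18, was found in 7 CD4 clonotypes (0.519%, CI 0.209 to 1.07) and 0 of 1138 CD8 clonotypes, which allows a share of up to 0.264% (exact permutation p = 0.031, adjusted p = 0.0422). The call of TRBV13 ended without single groups, at p = 0.0547 to 0.0703 without S1, S2, S3, S4, S5, S7 or S8 (exact permutation tests). The TRAV11-TRAJ18 clonotypes lay in 6 groups, and without any of these (S1, S2, S3, S5, S7 or S8) the exact test cannot give a p under 0.0625. The mean difference of -0.644 points was -0.724 to -0.501 without single groups. In run 1 TRAV11-TRAJ18 had p = 1 (exact permutation test). The alpha chain of mucosal-associated invariant T cells, TRAV1 with TRAJ33, was found in 1 clonotype of each class (exact permutation p = 1).

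V gene use over all clonotypes differed between the classes for 8 of 51 TRAV and 12 of 20 TRBV genes (edgeR). TRAV16N was found in 16.3% of CD8 and 4.38% of CD4 clonotypes (log2 ratio 1.95 ± 0.29 SE, adjusted p = 2.63e-09), higher in CD8 in 9 of 9 hashtag groups. TRAV12D-2 (6.06% against 1.56%) and TRAV9D-3 (3.34% against 1.19%) were also higher in CD8. TRAV5-4 was found in 3.25% of CD8 and 9.35% of CD4 clonotypes (log2 ratio -1.54 ± 0.32, adjusted p = 4.21e-05), lower in CD8 in 9 of 9 groups. TRAV5D-4, TRAV10N, TRAV4-2 and TRAV14N-3 were lower in CD8 as well, with log2 ratios from -2.05 to -1.54. Among beta chains, TRBV12-1 (4.22% against 0.519%, log2 ratio 2.92 ± 0.48, adjusted p = 6.50e-08), TRBV14 (7.12% against 1.93%, 1.94 ± 0.30, adjusted p = 3.84e-08), TRBV13-3 (9.75% against 4.01%) and TRBV3 (6.50% against 2.89%) were higher in CD8. TRBV20 (1.05% against 4.82%, -2.02 ± 0.40, adjusted p = 6.29e-06), TRBV15 (2.90% against 8.09%), TRBV1 (3.87% against 7.72%) and TRBV2 (2.72% against 6.01%) were lower. Without S6, 5 TRAV genes passed in the place of 8. TRAV9D-3 and TRAV4-2 did not pass when cells were counted or in run 1, nor TRBV1 when cells were counted or TRAV14N-3 and TRBV2 in run 1, and TRAV4-2, TRAV10N, TRAV14N-3 and TRBV2 did not with classes set from at least 2 UMIs. V genes that differ by few bases share reads, so members of families such as TRAV5-4 and TRAV5D-4 are less certain.

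**Figure D2:**
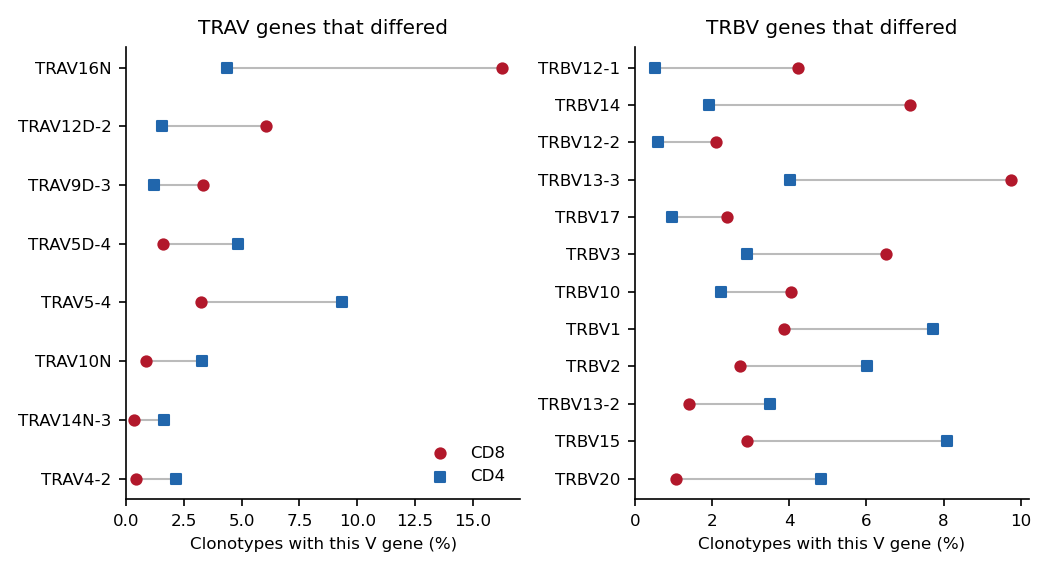
Percent of clonotypes (horizontal axis) that used each V gene (vertical axis) in CD8 T cells (circles) and CD4 T cells (squares), for the 8 TRAV and 12 TRBV genes that differed between the classes. TRAV16N reached 16.3% in CD8 against 4.38% in CD4, and TRAV5-4 9.35% in CD4 against 3.25% in CD8.

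Expanded clonotypes used some V genes more than single ones of the same class. Among CD4 clonotypes TRBV15 was found in 15.1% of expanded and 5.98% of single ones (log2 ratio 1.13 ± 0.26, adjusted p = 0.0013, edgeR), higher in 8 of 9 hashtag groups, the 1 call of 17 TRBV genes. It did not pass when cells were counted, in run 1 or with classes set from at least 2 UMIs, where 0 genes passed (3, 1 and 1 at unadjusted p under 0.05, edgeR), and without S6 3 genes passed. For the other tables TMM scaling gave 10 (CD8 TRAV, each lower in expanded clonotypes and none of them TRAV16N), 1 (CD8 TRBV, TRBV17, lower) and 0 (CD4 TRAV, 4 of 44 genes at unadjusted p under 0.05, edgeR) calls, and it also gave calls in many simulated tables with no difference. Without TMM, TRBV13-3 was found in 20.9% of expanded and 7.70% of single CD8 clonotypes (log2 ratio 1.47 ± 0.32, adjusted p = 0.000194), higher in 9 of 9 groups. TRAV16N was found in 27.7% against 14.2% of CD8 clonotypes (0.94 ± 0.27, adjusted p = 0.0271, higher in 8 of 9 groups) and TRAV5D-4 in 9.65% against 3.38% of CD4 clonotypes (1.41 ± 0.40, adjusted p = 0.0199, higher in 8 of 9 groups). TRBV17 was found in 0 of 177 expanded and 27 of 961 single CD8 clonotypes (2.81%, adjusted p = 0.0179). The values without TMM were not run under the other alternatives or with exchanged labels, which kept TMM. Their simulated tables held no spread between hashtag groups, so calls that such spread could give were not checked.

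Expanded CD8 T cells held fewer transcripts of Il7r, Lef1 and Ccr7 than single ones, and more of Ccl3, Ccl4 and Pdcd1. Il7r, the receptor of a survival cytokine, fell from 377 to 40.4 CPM (log2 ratio -3.30 ± 0.13 SE, adjusted p = 2.64e-11). Ccl3 and Ccl4, chemokines of activated T cells, rose by 3.76 ± 0.37 (330 against 25.3 CPM, adjusted p = 9.37e-07) and 3.36 ± 0.36 (1196 against 122 CPM, adjusted p = 2.16e-06) on the log2 scale. Pdcd1, the inhibitory receptor PD-1, rose by 2.16 ± 0.18 (396 against 91.1 CPM, adjusted p = 2.75e-07). The comparison was of 991 cells in expanded and 961 in single clonotypes of 9 hashtag groups, and 1024 of 3656 genes passed (470 up, 554 down, edgeR). Rises and falls are between UMIs summed over cells, and cannot tell a change within cells from a different mix of T cell states. The same holds for CD4 T cells and for the difference between the classes. The other large rises were of Nr4a2 (2.55 ± 0.24), a nuclear receptor induced by antigen, Dusp4, a MAP kinase phosphatase, Klre1 and Klrc1, receptors shared with natural killer cells, and Cenpf, Ube2c and Cdc20, which act in mitosis. Other large falls were of Dapl1 (-4.23 ± 0.28), Lef1 (-3.02 ± 0.17), a transcription factor of naive T cells, Ccr7 (-2.48 ± 0.24), a lymph node homing receptor, Kbtbd11, Sh3bp5, Rgcc, Rflnb and Sgk1. In GRCm38.p6, Pdcd1 lies on chromosome 1 at 94038305 to 94052553, Ccl3 on chromosome 11 at 83647843 to 83649378 and Il7r on chromosome 15 at 9506159 to 9529941. Cells of expanded clonotypes held more UMIs, with a median over groups of 2461 per cell against 1808. With cells thinned to 1000 UMIs, 471 of 1370 tested genes passed, and with cells that held Mki67 or Top2a UMIs left out, 609 of 2787.

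Of the gene lists, the naive and stem-like memory list had 15 of 16 measured members lower in expanded CD8 T cells and 1 higher, over all genes and adjusted over the list alone (camera adjusted p = 8.32e-12; adjusted p = 0.0196 with an estimated correlation). The 1 higher member was Xcl1 (1.79), a chemokine of activated CD8 T cells, and the 1 lower member of the cytotoxic list was Gzma (-0.98), a granzyme; both were named after their values were seen. The inhibitory receptor and exhaustion list had 13 of 14 members higher (14 adjusted over the list alone; adjusted p = 1.16e-11), with Nr4a2, Pdcd1, Eomes (1.72 ± 0.15), a transcription factor of effector and exhausted cells, and Rgs16 (1.91 ± 0.16). Its adjusted p was 0.0652 with an estimated correlation. Of the cytotoxic list 12 of 17 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 5.28e-06, and adjusted p = 0.160 with an estimated correlation), among them Klrc1 (2.08 ± 0.23) and Nkg7 (1.00 ± 0.10), a granule protein. Of the proliferation list 18 of 19 rose (19 adjusted over the list alone; adjusted p = 7.36e-11, and adjusted p = 0.173 with an estimated correlation), with Ccna2, a cyclin, and Hmgb2 (1.60 ± 0.17). Of the interferon response list 10 of 13 fell (10 adjusted over the list alone; adjusted p = 8.55e-07, and adjusted p = 0.160 with an estimated correlation), with Igtp (-1.66 ± 0.16), a GTPase that interferon induces, and Ly6a (-1.86 ± 0.22), a surface protein. Of the Th1 list 6 of 14 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0234, and adjusted p = 0.286 with an estimated correlation), with Ccl5 (1.66 ± 0.19) up and Ifngr1 (-1.66 ± 0.19) down.

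In 5 other lists CD8 genes moved both ways, and camera called the dissociation stress list of these. Of the T cell receptor signal list 2 of 12 rose, Nr4a2 and Tnfrsf9 (1.67 ± 0.28), and Cd69 (-1.21 ± 0.11), an early activation marker, fell (adjusted p = 0.831; the list's median was -0.25 and its mean 0.12). Of the tissue residency list 3 of 8 rose, with Rgs1 (1.02 ± 0.16) and Cxcr6 (0.89 ± 0.27), and 2 fell (adjusted p = 0.626). Of the T follicular helper list 5 of 9 rose, with Tox2 (2.04 ± 0.24), Batf (1.27 ± 0.19) and Sh2d1a (0.96 ± 0.15), and 3 fell (adjusted p = 0.104). Of the regulatory T list 4 of 8 rose, with Tigit (1.97 ± 0.19), an inhibitory receptor, and 2 fell, with Izumo1r (-1.20 ± 0.24; adjusted p = 0.449; 4 and 3 adjusted over the list alone). Of the dissociation stress list 8 of 16 fell, with Ier2 (-0.89) and Zfp36 (-0.85), and 2 rose, with Ier3 (1.25; 9 and 2 adjusted over the list alone; adjusted p = 0.0140, and adjusted p = 0.436 with an estimated correlation). RNA of other cell types moved with these groups. Of antigen presenting cell RNA 5 of 10 genes fell, with Lyz2 (-1.56 ± 0.44) and H2-Ab1 (-1.13 ± 0.33; 7 adjusted over the list alone; adjusted p = 0.0285, and adjusted p = 0.455 with an estimated correlation). The B cell genes Cd79b (-1.70 ± 0.23) and Cd79a (-1.19 ± 0.25) fell, as did the insulin genes Ins1 (-0.75 ± 0.17) and Ins2 (-0.82 ± 0.19) among 15 islet genes (adjusted p = 0.167). For the T cell receptor signal, tissue residency, follicular helper and islet lists the counts adjusted over the list alone were the same.

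Expanded CD4 T cells shifted in part in the same direction. Lef1 fell by 2.53 ± 0.18 (SE) on the log2 scale (adjusted p = 3.16e-07) and Il7r by 2.06 ± 0.18. Lag3, an inhibitory receptor that binds MHC class II, rose by 1.73 ± 0.17 (661 against 201 CPM, adjusted p = 1.34e-05), and Pdcd1 by 1.16 ± 0.12 (adjusted p = 2.01e-05). Ifng, the main Th1 cytokine, rose by 1.66 ± 0.20, and the granule genes Gzmk (1.71 ± 0.19) and Nkg7 (1.64 ± 0.20) rose as well. The comparison was of 758 cells in expanded and 1037 in single clonotypes of 9 hashtag groups, and 234 of 4126 genes passed (105 up, 129 down, edgeR). Socs2, Rgs16, Nfil3, Tigit, Gpm6b and Eea1 complete the 10 largest rises. Igfbp4, S1pr1, a receptor for leaving tissue, Vps37b, Kbtbd11, Gramd3, Klf2 and Pja1 were among the 10 largest falls. Lag3 lies on chromosome 6 at 124904359 to 124912434 and Lef1 on chromosome 3 at 131110297 to 131224357 (GRCm38.p6). The median depth was 2155 UMIs per cell in expanded and 1682 in single clonotypes. Run 1 gave 42 genes of 1643 tested, a class set from at least 2 UMIs gave 20 of 2231, and without S2 151 genes passed. Among 3542 genes tested in both classes, 974 passed in CD8 and 202 in CD4 T cells, and 167 in both, 165 of them in the same direction. Independent lists of these sizes would share 55.5.

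Of the naive and stem-like memory list 11 of 15 members fell in expanded CD4 T cells (14 adjusted over the list alone; camera adjusted p = 7.72e-17), with Klf2 (-1.23 ± 0.14) and S1pr1 (-1.74 ± 0.21). Of the inhibitory receptor and exhaustion list 8 of 12 rose (10 adjusted over the list alone; adjusted p = 2.51e-11), with Rgs16 (1.42 ± 0.15) and Tigit (1.18 ± 0.15). Of the cytotoxic list 6 of 9 rose (7 adjusted over the list alone; adjusted p = 4.68e-09). Of the Th1 list 7 of 14 rose, with Bhlhe40 (0.97 ± 0.16), and Ifngr1 (-1.10 ± 0.20) fell (7 and 2 adjusted over the list alone; adjusted p = 0.000249). Of the T follicular helper list 6 of 16 rose, with Maf (0.88 ± 0.16), Cd200 (1.06 ± 0.20) and Tox2 (0.86 ± 0.17), and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 1.09e-05). These 5 lists were also called with an estimated correlation (adjusted p = 0.0120, 0.0166, 0.0201, 0.0284 and 0.0166). The lists share members, so they are not separate results. Nkg7 and Ifng are in both the cytotoxic and the Th1 list, and Pdcd1 and Tox2 in both the inhibitory receptor and the follicular helper list. Of the tissue residency list 4 of 9 rose, with Rgs1 (0.58 ± 0.10), Cxcr6 (1.05 ± 0.25) and Ahr (1.00 ± 0.24), and Cd69 (-0.48 ± 0.13) fell (4 and 1 adjusted over the list alone; adjusted p = 0.0453, and adjusted p = 0.230 with an estimated correlation).

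Of the proliferation list 0 of 20 members passed over all genes with edgeR or DESeq2 (10 at unadjusted p under 0.05 with edgeR, 6 up adjusted over the list alone), and Mcm6, a replication helicase subunit, had a log2 ratio of 0.46 (adjusted p = 0.0649). Camera called that list (adjusted p = 1.81e-06; adjusted p = 0.114 with an estimated correlation). Of the dissociation stress list 3 of 15 fell, Junb (-0.39), Ier2 (-0.49) and Zfp36 (-0.53; 6 adjusted over the list alone; adjusted p = 0.00287, and adjusted p = 0.0637 with an estimated correlation). With DESeq2 0 of these 15 passed. Of the interferon response list Ifi27l2a rose (0.35 ± 0.09) as 1 of 14 (1 up and 5 down adjusted over the list alone), and camera placed the list lower (adjusted p = 0.00287; adjusted p = 0.184 with an estimated correlation). Camera did not call the T cell receptor signal list (2 of 17 rose, Spry1 at 1.03 ± 0.21 and Egr2 at 1.06 ± 0.25, and Cd69 fell; 3 and 1 adjusted over the list alone; adjusted p = 0.75; median -0.02, mean 0.07) or the regulatory T list (2 of 12 rose, Tigit and Capg; adjusted p = 0.318; median -0.01, mean 0.12). With DESeq2 0 of the 17 receptor signal genes and 1 of the 12 regulatory T genes passed. Foxp3, the regulatory T cell transcription factor, had a log2 ratio of -0.45 ± 0.23 (adjusted p = 0.348). Of islet RNA, Pyy (-2.27 ± 0.54, adjusted p = 0.0165) fell as 1 of 15 genes (1 adjusted over the list alone), and camera called the list lower (adjusted p = 1.74e-05; adjusted p = 0.195 with an estimated correlation). Of antigen presenting cell RNA 0 of 13 genes passed with edgeR, DESeq2 or adjusted over the list alone (0 at unadjusted p under 0.05, edgeR), while camera called the list lower (adjusted p = 0.0351; adjusted p = 0.558 with an estimated correlation). Of B cell RNA 0 of 3 genes passed with edgeR or DESeq2 (0 at unadjusted p under 0.05, edgeR; camera adjusted p = 0.177).

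**Figure D3:**
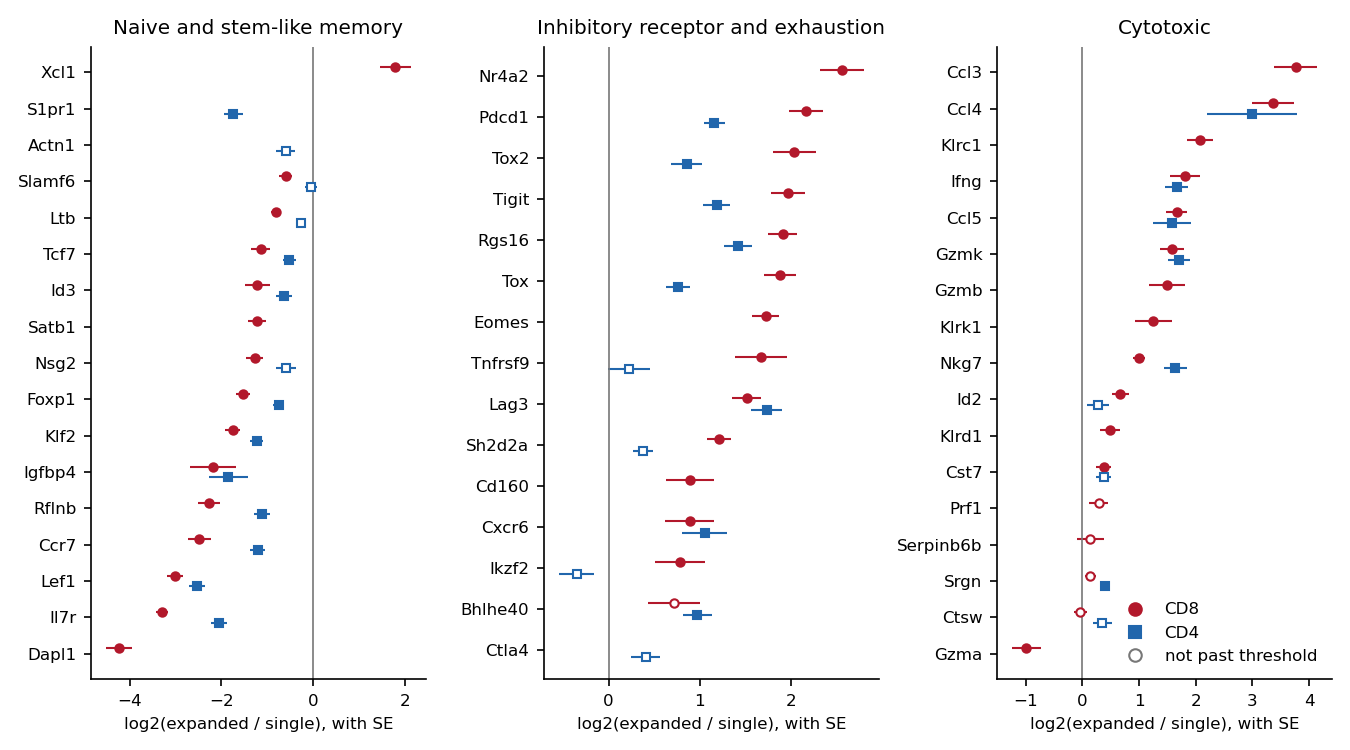
Log2 ratio of expanded to single T cells (horizontal axis, bars are SE) for members shown of the naive, inhibitory receptor and cytotoxic lists (vertical axis), with circles for CD8 and squares for CD4 T cells and open symbols for genes that did not pass the threshold. Il7r lay at -3.30 in CD8 and -2.06 in CD4, and Pdcd1 at 2.16 in CD8 and 1.16 in CD4.

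The difference between these changes was tested itself, and 211 of 4651 genes passed (58 higher and 153 lower in CD8 relative to CD4, edgeR). The fall of Il7r was larger in CD8 T cells (difference -1.31 ± 0.31, adjusted p = 0.0118), as was the rise of Pdcd1 (1.02 ± 0.23, adjusted p = 0.00729). Among proliferation genes Hmgb2 (1.33 ± 0.29, adjusted p = 0.00657), Ccna2 (1.51, adjusted p = 0.0232), Cenpa (1.45, adjusted p = 0.0183) and Mcm6 (0.82, adjusted p = 0.0223) changed more upward in CD8. Among interferon genes Igtp (-1.26 ± 0.20, adjusted p = 0.00035) and Ly6a (-1.36 ± 0.30) changed more downward, as did Sh3bp5 (-2.24 ± 0.33) and Rgcc (-2.54 ± 0.43). Foxp3 differed by -2.70 ± 0.67 (adjusted p = 0.0143). B cell RNA moved with these genes, since Cd79b differed by -1.79 ± 0.40 (adjusted p = 0.00821). For Lef1 (-0.47, adjusted p = 0.487), Lag3 (-0.20), Nkg7 (-0.65, adjusted p = 0.128) and Ifng (0.18) no difference was detected at this depth. Without S1, 109 genes passed, without S3 118 and without S9 136, and with cycling cells left out 71.

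Beta-like cells of the hashtag groups carried more transcripts of the unfolded protein response and of the interferon response than alpha-like cells of the same groups. All 17 measured unfolded protein response genes were higher (17 adjusted over the list alone; camera adjusted p = 8.59e-12, and adjusted p = 0.0950 with an estimated correlation). Sdf2l1 and Hyou1, chaperone system members of the endoplasmic reticulum, had log2 ratios of 2.77 ± 0.10 (SE, 9 groups) and 1.94 ± 0.09, Pdia6, a disulfide isomerase, 1.79 ± 0.08 and Atf5, a stress transcription factor, 2.81 ± 0.10. Xbp1 was higher by 0.49 ± 0.07 and Herpud1 by 0.22 ± 0.09 (adjusted p = 0.0366). Of 17 interferon response genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 2.06e-06, and adjusted p = 0.0950 with an estimated correlation). Gbp2, an interferon-induced GTPase, stood at 181 against 34.1 CPM (2.39 ± 0.12, adjusted p = 4.61e-16), with Igtp (1.91 ± 0.11), Gbp4 (2.20 ± 0.13) and Isg20 (0.91 ± 0.08) also higher. Ifi27l2a was lower (-1.25 ± 0.26).

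Of 20 antigen presentation genes 13 were higher in beta-like cells and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 0.00295, and adjusted p = 0.491 with an estimated correlation). Calr (0.81 ± 0.06), Pdia3 (0.74 ± 0.06) and Tapbp (0.63 ± 0.07), which load peptides on MHC class I, were higher, as was Tap1 (0.85 ± 0.10), which carries peptides. B2m, the light chain of MHC class I, was lower, at 1332 against 2344 CPM (-0.79 ± 0.07, adjusted p = 2.90e-11). Of the checkpoint ligand list 2 of 9 were higher and 1 lower (adjusted p = 0.418): Cd274, which encodes PD-L1, stood at 27.7 against 8.03 CPM (1.64 ± 0.18, adjusted p = 6.57e-09), Cd47 at a log2 ratio of 0.23 ± 0.08 and Socs3 at -0.95 ± 0.14. Of 3 measured chemokines Cxcl10, which draws CXCR3-bearing T cells, was higher (1.26 ± 0.29, adjusted p = 0.000517, in 7 of 9 groups), and Cx3cl1 (-2.69 ± 0.24) and Ccl5 (-0.78 ± 0.26) were lower (list adjusted p = 0.418). Adjusted over the list alone, the counts of these lists were the same. Of the 2185 beta-like and 2209 alpha-like cells, those of no hashtag group were not tested. The groups held 58 to 194 beta-like and 44 to 388 alpha-like cells each. Their median UMI counts were 4981.5 to 17277 in beta-like and 4868 to 7417.5 in alpha-like cells. With the cells of no hashtag group, the medians were 1542 over all beta-like and 5509 over all alpha-like cells. The beta-like cells tested were thus deeper than the class as a whole, and the results do not cover the others. Receptor contigs were found in 62.1% of a beta-like cluster of 87 cells and 77.6% of an alpha-like cluster of 152 cells, and Ccl5 is also made by T cells.

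**Figure D4:**
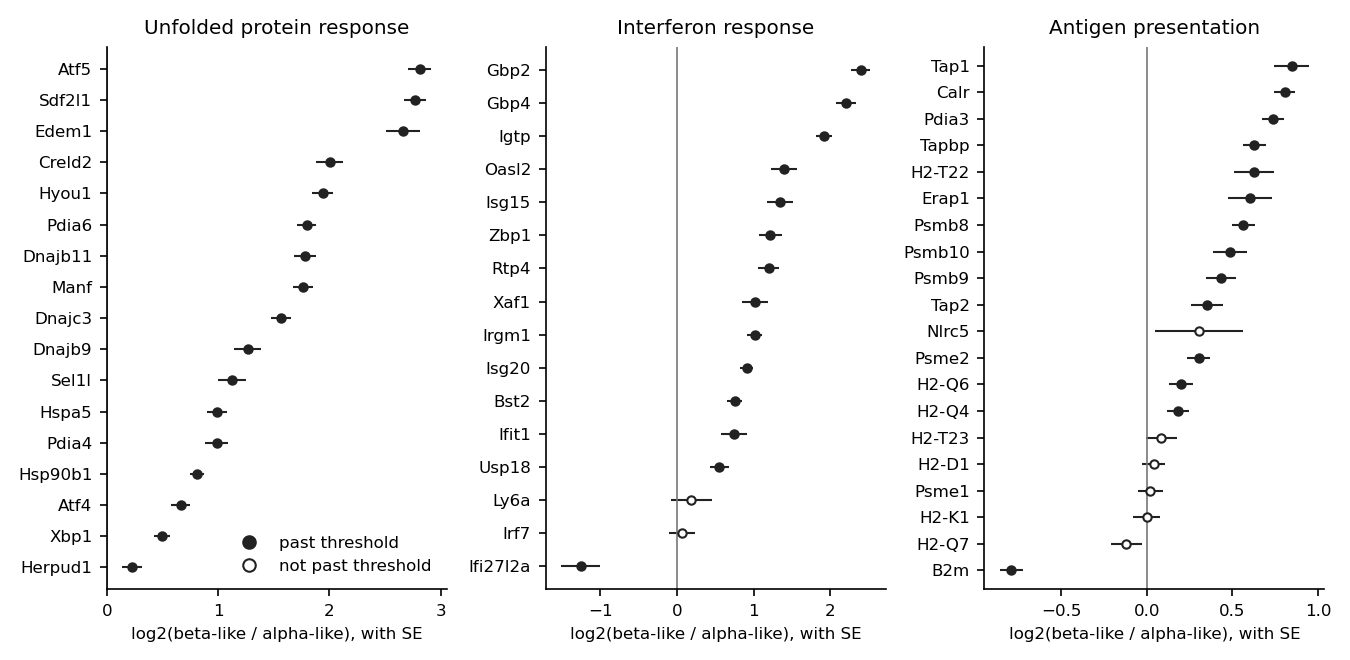
Log2 ratio of beta-like to alpha-like cells (horizontal axis, bars are SE over the fit of 9 hashtag groups) for members shown of the unfolded protein response, interferon response and antigen presentation lists (vertical axis), with open symbols for genes that did not pass the threshold. All 17 unfolded protein response genes lay above 0, from 0.22 for Herpud1 to 2.81 for Atf5, and B2m lay at -0.79.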

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

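Of the tests in this part, the count of TRA UMIs was chosen before its result was seen, and the other tests of explanations and the exchanges of labels were chosen only after the results were seen.

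The acinar-like share was 8.154% in library 1 and 0.725% to 1.29% in the others, a gap larger than 4 libraries of 1 pool usually show. In run 1 it was 4.39% in library 1 and 0.508% to 0.966% in the others, and with the stricter filter on cells 2.55% and 0.19% to 0.480%. The beta-like share was 8.472% in library 2 and 7.26% to 7.33% in the others. Mature dendritic-like cells were 3.303% of hashtag group S8, where the next group had 2.03% and the median was 1.36%. Plasma cell-like cells were 1.491% of S7, with 0.903% in the next group. The largest CD4 clone held 10.39% of the CD4 T cells of S8, against 6.31% in the next group. These 5 were the values that stood apart among 53 groups of values, where chance gives about 1 in 20. The test of the difference between CD8 and CD4 T cells gave 211 genes whose expanded against single change differed between the classes.

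A paired receptor of CD4 T cells, TRAV16N-TRAJ23 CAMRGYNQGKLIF with TRBV15 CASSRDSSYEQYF, was found with the same CDR3 nucleotides in 31 cells of S2 and 15 of S9. Of its cells, 24 were classed CD4 and 1 CD8. Hashtag spill would move cells of other clonotypes too, but of the 10 other clonotypes of at least 10 cells in S2, with 173 cells, 0% of cells lay in S9. Nor was 1 animal with 2 hashtags borne out, since 0% of 43 other clonotypes of at least 5 cells in either group, with 418 cells, lay in both. The same receptor formed separately in both animals is a possible explanation that stays open, as does a sequence carried over in handling. No biological explanation was tested, since the design gives no group for the hashtags.

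The alpha chain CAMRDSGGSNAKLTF of the TRAV16-TRAJ42 family recurred in 23 CD8 clonotypes of 8 hashtag groups, where a clonotype in 2 groups counts in each. Free receptor RNA from a large clone could give other cells that chain at a low UMI count. With the largest clonotype of each group left out, its 36 cells in 15 clonotypes had a median of 11 TRA UMIs (range 1 to 55). The median was 7 in 1743 other CD8 T cells (range 1 to 63), a ratio of 1.571, which speaks against that source for the 36 cells as a set. Cells with more than 1 TRA chain had been left out, so single cells with few UMIs are not settled. Selection by a shared antigen stays open as a hypothesis, and no antigen was measured here.

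Changes of genes in expanded CD8 T cells were weighed against cycling cells, depth per cell and a few large clonotypes, on the 29 called members of the naive and the inhibitory receptor lists. With cycling cells left out, 25 passed (86.21%). For depth per cell, cells under 1000 UMIs were left out and every other cell was thinned to 1000 UMIs. Then 18 of the 20 members still tested passed (90%). With a few large clonotypes left out, the 5 largest of each class, 28 passed (96.55%). Depth per cell was thus not the whole cause for those 18 members among cells of at least 1000 UMIs, nor were the 5 largest clonotypes for those 28. Either can still hold a part, since a member that passes can have lost some of its change. Cycling cells without a UMI of Mki67 or Top2a were kept, so their part cannot be settled. The proliferation genes, which follow cycling cells, and RNA of other cell types stay open too. So does the mix of T cell states, such as the share of naive cells among single clonotypes, which was not tested.

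Labels were exchanged within hashtag groups in 100 splits, the real one included. Only 1 split, the real one, gave as many genes for CD8 T cells (1024, highest other 445), CD4 T cells (234, highest other 27), their difference (211, highest other 10) and beta-like against alpha-like cells (3602, highest other 2108), or as many V genes between CD8 and CD4 clonotypes (8 TRAV, highest other 3; 12 TRBV, highest other 8). For expanded CD8 clonotypes the V gene counts were reached by 1 split (TRAV, 10, highest other 1) and 3 splits (TRBV, 1, highest other 2), so exchanged labels rarely gave them. Simulated tables with no difference gave calls in 65% and 30% of cases for these 2 tables, so TMM scaling stays open for them. Chance can be excluded for the counts given before these 2 tables, apart from those of islet cells and of the difference. Beta-like and alpha-like classes were clustered from the same counts, so the real labels had to stand out there. For the difference, the exchange swapped CD8 and CD4 labels, whose own differences then widened the spread. Neither exchange can decide, nor can that of single islet cell lists. Chance cannot be excluded for the TRBV genes of expanded CD4 clonotypes, reached by 9 splits (1, highest other 3). For their TRAV genes the count was 0 (highest other 1), which all 100 splits reach whatever the data, so the exchange tests nothing there. For the number of gene lists called in CD4 T cells (11 lists, 2 splits, highest other 12), it can be excluded for the count but not for each list counted. It cannot for the count in CD8 T cells (8 lists, 16 splits, highest other 9) or in islet cells (3 lists, 42 splits, highest other 4). For single lists, a p as small was given by 1 split for the naive and the inhibitory receptor lists in both T cell classes and for the unfolded protein and interferon response lists in islet cells. In CD8 T cells it was given by 6 splits for the proliferation and interferon lists, 7 for the cytotoxic, 15 for the Th1, 27 for the dissociation stress and 41 for the antigen presenting cell RNA list. In CD4 T cells it was given by 1 split for the cytotoxic list, 2 for the Th1, 4 for the follicular helper, 5 for the dissociation stress, 6 for the proliferation, 15 for the tissue residency, 19 for the interferon, 26 for the islet RNA and 56 for the antigen presenting cell RNA list. In islet cells it was given by 34 for the antigen presentation list. The median log2 ratio of a list is a second measure, and for the naive, inhibitory receptor, unfolded protein and islet cell interferon lists 1 split gave one as large. In CD8 T cells 1 split did for the proliferation, cytotoxic and Th1 lists (1.44, 1.00 and 0.64, largest other 1.26, 0.98 and 0.49), 2 for the interferon and dissociation stress lists and 7 for antigen presenting cell RNA. In CD4 T cells 1 did for the cytotoxic and proliferation lists, 2 for the Th1 and follicular helper, 4 for the interferon, 5 for the tissue residency, 9 for the dissociation stress, 17 for the islet RNA and 30 for the antigen presenting cell RNA list. In islet cells 3 did for the antigen presentation list. Lists that camera did not call in CD8 T cells also had medians that few splits reached. These were T cell receptor signal (-0.2505, 1 split, largest other 0.248), follicular helper (2 splits) and tissue residency (3 splits). A p as small was given there by 85, 19 and 57 splits. A median that few splits reach therefore does not alone exclude chance for a list, and no correction covered the lists and measures. Chance stays open for each p or median reached by 5 or more.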

How the results depend on the processing

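Of the alternatives here, those with other Scrublet scores, clone sizes counted in other ways, T cell-like clusters alone, the largest clonotypes left out, the library as unit, other minimums and all gene list counts of other cell sets were chosen only after the data were seen. Of 340 alternative values of the main results, 249 were labelled the same and 91 changed. Counts of genes, lists and V genes were the same within 1.5 times the main count, and shares of cell classes within the SD over libraries. Tests of CD8 against CD4 shares were the same with an unchanged direction and side of the threshold, or if neither passed. Sharing between libraries needed the same side alone. Over 119 pairs of a named gene and a comparison, 2719 alternative values were the same, 81 stronger, 122 weaker and 1 reversed, and for single lists 406, 10, 46 and 5. Keeping the cells that Scrublet marked left all 152 of its values as they were, so it tests nothing and is not counted. The causes were not tested, except that run 1, thinning and left-out cells leave fewer genes to test or fewer UMIs.

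For genes in expanded CD8 T cells (1024), run 1 gave 537, thinning 471, cycling cells left out 609 and the library as unit 1910. Of the 1024 calls, run 1 tested 705 and kept 476, thinning tested 560 and kept 384, and DESeq2 kept 766. In CD4 T cells (234), run 1 gave 42, TRB alone 397, classes from at least 2 UMIs 20, T cell-like clusters alone 398 and no filter on counts 403. Leaving out hashtag groups gave 151 (S2) to 252 (S8). For the difference (211), run 1 gave 101, expansion from 3 cells 396, thinning 101, cycling cells left out 71, the library as unit 510 and left-out groups 109 (S1) to 214 (S6). DESeq2 gave 770, 161 and 241. Beta-like against alpha-like cells (3602 genes) gave 2373 in run 1, where 4877 genes were tested in the place of 7196.

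With an estimated correlation, 1 list was called in CD8 T cells, 5 in CD4 T cells and 0 in islet cells (limma, unadjusted p = 0.0316 and 0.0380 for the unfolded protein and interferon lists). Classes from at least 2 UMIs gave 5 lists in CD4 T cells. In CD4 T cells the mean log2 ratio of antigen presenting cell RNA turned to 0.0751 in run 1, 0.0180 with thinning and 0.169 in T cell-like clusters alone. That of the interferon list turned to 0.0434 and that of Zfp36 to 0.0285 with classes from at least 2 UMIs, and that of the tissue residency list to -0.0126 in run 1.

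The mean CD8 minus CD4 difference in expanded share (6.76 points) became 10.2 with expansion from 3 cells (exact permutation p = 0.0469), 13.2 with clone size among classed cells and 12.7 with equal cell numbers as well (exact permutation p = 0.0156). Both settings with clone size among classed cells drop cells of neither class, so they cannot be told from weaker detection of the CD4 class gene. With the 5 largest clonotypes of each class left out the mean difference became 3.97, with a median of -0.872 and a higher CD8 share in 4 of 9 groups (exact permutation p = 0.410). Without the replicate block p was 0.313 (permutation test). Sharing between libraries gave 434 in run 1, 293 for 3 or more cells and 592 with TRB alone. TRAV11-TRAJ18 gave -0.223 points in run 1 and -0.724 to -0.501 without single groups, the TRBV13 family 2.57 to 3.94 without single groups, and TRBV1 -1.21 with cells counted.

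V genes that differed between CD8 and CD4 numbered 5 (without S6) to 9 (without S8) for TRAV. For expanded against single clonotypes, CD8 TRAV (10) gave 1 without TMM, 1 and 0 with minimums of 5 and 20 clonotypes, 16 with cells counted, 2 in run 1, 0 from 2 UMIs and 0 (S1 to S5) to 9 without single groups. CD8 TRBV (1) gave 2 without TMM, 4 with no replicate block, 2 and 3 with the minimums, 9 with cells counted, 0 in run 1, 5 from 2 UMIs and 1 to 7 (S7) without single groups. CD4 TRAV (0) gave 1 without TMM, 1 with no replicate block, 1 and 1 with the minimums, 2 in run 1 and 0 to 3 (S2) without single groups. CD4 TRBV (1) gave 0 with cells counted, 0 in run 1, 0 from 2 UMIs and 1 to 3 (S6) without single groups. Where these counts were 0, 0 to 14 genes had an unadjusted p under 0.05 (edgeR). The replicate block, here the hashtag group, pairs cells of 1 animal. Without the replicate block 1160 genes passed in CD8 and 232 in CD4 T cells and 183 for the difference. Apart from the V gene counts of expanded CD8 TRBV and CD4 TRAV clonotypes given here, it changed no count by over 1.5 times. The antigen presenting cell list was then not called in CD8 (adjusted p = 0.0737, limma) or CD4 T cells (0.12), nor the tissue residency list in CD4 T cells (0.0645).

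Of cells, T cell-like were 17.7% in run 1 and 16.2% with a minimum score of 0.55, B cell-like 19.6% at resolution 0.5 and 19.7% with doublets kept, beta-like 5.55% with the strict filter and 6.10% in run 1, alpha-like 8.33% and 8.87%. Plasma cell-like cells (0.781%) were 1.61% in run 1, acinar-like cells (2.77%) 1.70% in run 1, 0.898% with the strict filter and 4.80% with no minimum score, and cells like those that make pancreatic polypeptide (0.394%) 0.666% with doublets kept. No cluster had that last name in run 1, with the strict filter or at resolution 0.5, where natural killer-like, mature dendritic-like and type 1 conventional dendritic-like clusters were missing too. Unnamed cells were 13.1% at resolution 0.5, 22.5% in run 1, 25.0% with the minimum of 0.55 and 2.74% with none. The comparison of diets and its alternatives were not run. At this depth 48.2% of paired T cells showed no UMI of the class genes and are in neither class.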

Other observations

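Of the receptors, the TRAV16-TRAJ42 alpha chains of CD8 T cells were concentrated in expanded clones, a count chosen after the data were seen. They were found in 29 of 177 expanded CD8 clonotypes (16.4%), which held 286 of 991 cells (28.9%), and in 15 of 961 single clonotypes (1.56%). The 44 clonotypes, where 1 in 2 hashtag groups counts in each, used 16 alpha CDR3s and 36 beta CDR3s. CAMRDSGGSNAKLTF was found in 23 of them (52.3%), in 8 hashtag groups, 3 nucleotide forms and 17 beta CDR3s, with 209 cells. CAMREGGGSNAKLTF and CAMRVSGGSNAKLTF were found in 3 clonotypes each. The beta chain was TRBV13-3 in 23 clonotypes (52.3%) and TRBV3 in 7 (15.9%). The family made up 9.35%, 17.9%, 30.7%, 11.1%, 10.3%, 17.4%, 8.73%, 1.30% and 17.2% of CD8 T cells in S1 to S9. Beside the CD4 receptor in S2 and S9, 2 more clonotypes had at least 2 cells in each of 2 groups: TRAV16N-TRAJ42 with TRBV13-3 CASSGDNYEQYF (7 CD8 T cells of S4 and 5 of S1) and TRAV5-4 with TRBV5 (3 of S7 and 2 of S4). A further 20 receptors with the same amino acids lay in at least 2 groups with at least 2 nucleotide forms. Of 282 clonotypes of at least 3 cells that included a CD8 or CD4 T cell, 8 held both CD8 and CD4 T cells.

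Other cell types of the islets were mesenchymal-like (3.13% ± 0.233, SD over 4 libraries), endothelial-like (2.37% ± 0.226), ductal-like (1.20% ± 0.0976), pericyte-like (0.723% ± 0.180) and Schwann-like cells (0.264% ± 0.0540), and cells like those that make pancreatic polypeptide (0.394% ± 0.0724). Type 1 conventional dendritic-like cells were 1.12% ± 0.0799 and plasma cell-like cells 0.781% ± 0.0423 (1.61% in run 1). Of unnamed clusters, one of 1068 cells was led by S100a4, Mcemp1, Ifitm6 and Cfp. T cell-like clusters were led by Lef1 and Ccr7 (3630 cells), by Izumo1r, Tnfrsf4 and Ctla4 (2489 cells), by Ccl5, Xcl1 and Cd8a (1455 cells), by Il7r, Cxcr6 and Cxcr3 (1053 cells) and by Ube2c, Birc5 and Rrm2 (708 cells).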
